A study of Mus musculus with 8 samples.

How the data were processed

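RNA from mouse peritoneal macrophages treated with LECT2 was hybridised against RNA of untreated cells on 8 2-colour Agilent arrays, 4 to a slide on 2 slides. Per the labels the cells were kept in medium with 20% serum, LECT2 was labelled with Cy3 and the control with Cy5 on every array, and no dye swap was made. The sample titles give the early time as 3.5 h and the channel labels as 3 h; 3.5 h is used here. Each of the 4 groups had 2 arrays, from 2 independent experiments with different mice, which the replicate numbers identify.

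Per the file headers the slides were read by Agilent Feature Extraction 10.7.3.1, and the scanner files hold the median spot and background intensity of each channel, the processed intensity (background-subtracted and dye-normalised within the array) and the log10 ratio of Cy5 over Cy3. The files held no mean spot signal, so median signals took its place. The deposited values are in log2 units, with 1 column for each sample. Its labels do not state how it was made, and its values were compared with the scanner files. The 4 columns of the 48 h arrays equal the software's ratio of Cy5 over Cy3 within 0.01. Of the 3.5 h columns 3 follow a file at r = 0.994, 0.996 and 0.995 without being equal to it, so the columns of the 2 times may have been made differently. In 7 of the 8 columns the best-matching file is recorded under another sample, and the column of the low dose at 3.5 h, replicate 1, follows its own file at r = 0.819 only.

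The design fixed before the data were examined called for the scanner files, normexp background correction and loess. Because of the conflict between columns and files, the value table was made the main source before any count of genes was seen, with its sign reversed so that a positive value is LECT2 over control. Scanner files matched to the columns, and the files as recorded, were run as alternatives, all chosen after the data were seen. Under the matched link slide 1 holds all 3.5 h arrays and slide 2 all 48 h arrays, and under the recorded link each slide holds 1 replicate of every group. The gene lists, the filter, the probe rule, the tests and the other alternatives were set before the data were examined.

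Each array has 44397 spots, 43020 of them for 39429 probes and 1377 for controls, and 39428 probes are in the table. Probe accessions were looked up in a RefSeq gene table of assembly GRCm38.p6, used for names only (the array annotation is on mm9), which named 26412 probes and left 13017 unnamed. Probes well above background in either channel on at least 2 of the 8 arrays were kept (31615), and for the 4259 genes with several probes the brightest was used, leaving 26148 genes tested, 16754 of them with a symbol. In the comparisons with control 62 called results of named genes had other probes, and in 4 of them at least 1 other probe moved the opposite way (Idi2 and Fdft1 at the low dose and 3.5 h, Zbtb46 and Rpl6 at the high dose and 3.5 h). Among the differences the same held for Siglec1 between times at the high dose and for Klra8 between doses at 3.5 h. Outlier spots made up at most 1.42% of an array. Column medians of the table lay between -0.22 and 0.08, and ratios of the 2 replicates correlated across genes at r = 0.414, 0.721, 0.352 and 0.620 for the low and high dose at 3.5 h and the low and high dose at 48 h.

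Tests were made with limma 3.58.1 in R 4.3.3 (tables read with data.table version 1.17.8), with 1 mean per group, moderated variances on 4 residual degrees of freedom and Benjamini-Hochberg adjustment over all genes at 0.05. The 4 group means, the 2 dose differences (high minus low) and the 2 time differences (48 h minus 3.5 h) were tested. The control channel was compared between times from the matched files after quantile scaling, with the arrays of a time and replicate averaged (26039 genes, 2 residual degrees of freedom). A replicate block with sum-to-zero coding was the paired alternative (3 residual degrees of freedom). Deviations of the replicates from their group mean correlated between groups at r = 0.04, 0.17, 0.20, 0.00, -0.06 and 0.47, so not every pair was above 0.1 and the unpaired fit was kept as the main one. The 0.47 was between the low and high dose at 48 h, so the unpaired dose difference at 48 h leaves this pairing unused.

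The 29 gene lists (696 members) were tested in the 9 comparisons (261 tests, adjusted together) with camera from limma at a preset correlation of 0.01. With an estimated correlation 0 of the 83 calls held. Genes reported by name followed a rule: the 10 largest called changes in each direction (5 for a difference), up to 4 called members of each list, and Cd209a, Tnf, Il1b and Arg1 in every case. Not every gene under this rule is reported here. Where 1 channel was not above background, a fold is given as a bound, with the dim channel set to the lowest signal well above background on that array, and no fold is given where both channels were dim. In a leave-one-out run the remaining array of a group is assumed to vary like the arrays of the other groups.

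On simulated data with added changes of log2 1, 2 and 4, the test recovered 3.17%, 85.2% and 100% at the low dose and 3.5 h, with 7 false of 137 calls. Dose differences at 48 h were recovered at 0%, 29.4% and 98.6%, and time differences at the high dose at 0%, 26.5% and 97.1%. The control-channel test made 27 false of 185 calls, above the 5% aimed at. For the low dose at 48 h alone, lists shifted by log2 1 were called in 20 of 20 draws and unshifted ones in 4 of 560, and the list test was not simulated for other shifts or comparisons. Simulated genes were drawn independently, so these draws cannot show how often the list test errs when genes of a list vary together.

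Alternatives covered the replicate block, Agilent processed signals, no background correction, median centring in place of loess on the matched files, Aquantile scaling, outlier spots kept, no or a strict filter (both channels above background on all 8 arrays, 20622 probes), the mean over probes, every probe, centred columns, a trended robust variance, only the groups compared, 2-fold thresholds and each array left out. Named genes and lists were not run on the files as recorded, except for the count of list calls.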

Results

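Peritoneal macrophages, the resident phagocytes of the abdominal cavity, were taken from mice and cultured with recombinant LECT2 (leukocyte cell-derived chemotaxin 2, a secreted protein made mainly by the liver) at 0.5 µg/ml, called the low dose here, or 5 µg/ml, called the high dose, or with none. RNA was measured after 3.5 h or 48 h on 8 Agilent arrays, each carrying a LECT2 sample in one dye and a control sample in the other. The arrays formed 4 groups of 2 arrays (low and high dose at 3.5 h, low and high dose at 48 h), and the 2 arrays of a group came from 2 independent experiments with different mice. Between 56.4% and 71.7% of the non-control spots were above background in the LECT2 channel and between 63.6% and 82.3% in the control channel, and 26148 genes were tested. The number of arrays limits the precision: the median standard error was 0.28 on the log2 scale for an effect and 0.40 for a difference between 2 effects.

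The comparisons asked which genes LECT2 changed at each dose and time, whether the dose changed the response, and whether the early and late responses differed. The deposited values are control over LECT2, opposite to the wording of the titles, and all values here are turned round, so a positive log2 value means more transcript with LECT2. Values are means of 2 arrays (n = 2) ± SE, and every gene said to rise or fall moved the same way on both arrays, with an adjusted p from limma under 0.05 over all genes tested. The control sample carried the same dye on every array, so a dye effect equal on every array cannot be told apart from an effect of LECT2 for a single transcript, except where its change differs between doses or times. Median centring here means the matched scanner files with normexp and median centring in place of the table. The median of all genes was then log2 -0.13 and -0.25 at 3.5 h and -0.14 and -0.24 at 48 h (low and high dose), so directions given under it are to be read against these shifts.

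**Figure D1:**
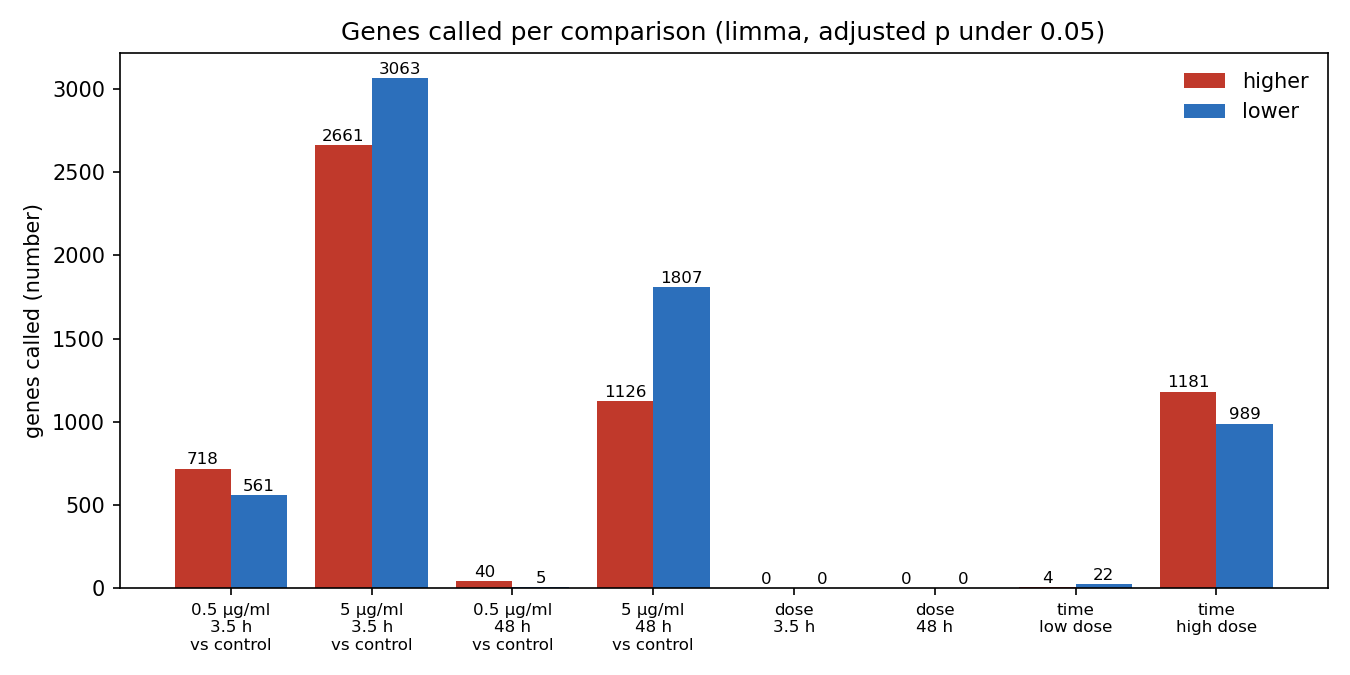
Number of genes (vertical axis, genes) higher and lower in the 4 comparisons with control, the 2 dose differences and the 2 time differences, at an adjusted p under 0.05 from limma. The high dose at 3.5 h gave the most genes (2661 higher and 3063 lower) and the 2 comparisons of doses gave 0.

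At 3.5 h the low dose turned on genes of acute inflammation. Tnf, the prototype inflammatory cytokine of macrophages, rose 47.9-fold (log2 5.58 ± 0.36, adjusted p = 0.00154) and Il1a rose by log2 5.69 ± 0.41 (adjusted p = 0.00186). Il1b rose by log2 3.02 ± 0.46 (adjusted p = 0.0143), and the neutrophil growth factor Csf3 by 5.26 ± 0.49 (adjusted p = 0.00356). Il23a, which drives T cells that make interleukin 17, rose at least 11.7-fold (adjusted p = 0.000648) from a control signal at background. Ptgs2, the inducible cyclooxygenase, rose by log2 4.48 ± 0.44, Lif by 4.49 ± 0.39 and Ch25h, which makes 25-hydroxycholesterol, by 4.71 ± 0.70 (adjusted p from 0.00262 to 0.0141).

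Chemokines that attract T cells and monocytes rose too. The log2 changes were 3.91 ± 0.48 for Cxcl10, 3.65 ± 0.32 for Ccl3 and 3.48 ± 0.29 for Ccl5. Interferon-stimulated genes rose with 2.91 ± 0.25 for Ifit2 and 3.39 ± 0.27 for Gbp5. The costimulatory receptor gene Cd40 rose by log2 2.82 ± 0.25 and Acod1, the gene for the itaconate-making enzyme of activated macrophages, by 3.59 ± 0.39.

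Rgs2, a brake on G-protein signalling, fell 16.2-fold (log2 -4.02 ± 0.24, adjusted p = 0.00151). The receptor gene Cd300lb fell as well (log2 -3.34 ± 0.28, adjusted p = 0.00239), as did the checkpoint gene Vsir (-3.13 ± 0.23, adjusted p = 0.00196). Abcg1, which exports cholesterol, fell (log2 -1.41 ± 0.29, adjusted p = 0.0389), and so did the immediate early gene Fos (log2 -2.80 ± 0.52, adjusted p = 0.0277). Cd209a, a C-type lectin gene, was at log2 -1.61 ± 0.45, not past the threshold (adjusted p = 0.0871), but was past it with the replicate block (adjusted p = 0.031, and from 0.0134 to 0.563 over its alternatives). Arg1, a gene of alternative activation, spread widely at log2 -1.97 ± 1.13 (adjusted p = 0.361, 0.0112 with the replicate block, and from 0.0112 to 0.93 over its alternatives).

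Of 30 targets and feedback genes of NF-kB, the central inflammatory transcription factor, 23 were higher, 0 lower and 7 not past the threshold at the low dose and 3.5 h. Adjusted over the list alone 29 were higher, and the median log2 change was 2.11, or 2.10 with a member at background held at its bound (adjusted p = 1.94e-28, and adjusted p = 0.763 with an estimated correlation). Of 36 interferon-stimulated genes 22 were higher (30 adjusted over the list alone). The median log2 was 1.58 (adjusted p = 1.05e-23; adjusted p = 0.763 with an estimated correlation). Among 19 proinflammatory cytokines 11 were higher (16 adjusted over the list alone). Their median log2 was 2.77 (adjusted p = 1.04e-15, and 0.763 with an estimated correlation). Chemokines had 8 of 25 higher (14 higher and 1 lower adjusted over the list alone). The group had a median log2 of 1.29 (adjusted p = 8.98e-07, and 0.783 with an estimated correlation). Antigen presentation moved less, with 2 of 26 higher (8 adjusted over the list alone) and a median log2 of 0.57 (adjusted p = 0.000376, and 0.783 with an estimated correlation). Median centring ended its call (0.05, adjusted p = 0.102).

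Lower at this dose and time were cholesterol efflux and lipid storage (3 of 25 lower and 1 higher, or 8 lower and 2 higher adjusted over the list alone, median log2 -0.51, adjusted p = 0.0102, and 0.763 with an estimated correlation) and macrophage identity (2 of 20 lower and 1 higher, or 5 and 1 adjusted over the list alone, median log2 -0.72, adjusted p = 0.0107, and 0.783 with an estimated correlation). The cell cycle list was lower as a group (median log2 -0.41, adjusted p = 0.0134, and 0.911 with an estimated correlation), with 1 of 36 genes lower, Cenpa at log2 -1.49 ± 0.24, and 1 higher, Mki67 at 2.42 ± 0.37 (6 lower and 1 higher adjusted over the list alone). Markers of T and NK cells were slightly higher (median log2 0.50, or 0.45 with members at their bound, adjusted p = 0.00557, and 0.763 with an estimated correlation), with 1 of 21 past the threshold, Cd247 at 1.08 ± 0.23 (2 adjusted over the list alone). Without the background filter this list was not past the threshold (adjusted p = 0.0838). Markers of red blood cells gave 2 of 7 higher, Hbb-b2 at log2 1.93 ± 0.30 and Hba-a2 at 1.23 ± 0.26 (0.76 without replicate 1), while the list missed the threshold (median log2 1.23, adjusted p = 0.1), as did mesothelium and fibroblasts (median log2 -0.89, adjusted p = 0.0538).

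In all, limma called 1279 genes for the low dose at 3.5 h, 718 higher and 561 lower. Fitting only the arrays of this group gave 0 (4665 at an unadjusted p under 0.05), no filter 733, a trended robust variance 753 and the matched files under loess 2374. Leaving out replicate 1 gave 117 genes, and leaving out replicate 2 gave 1372, of which 546 were among the 1279. Of 71 named calls 24 and 48 remained past the threshold. With the scanner files taken as recorded under each sample, limma called 0 genes (952 at an unadjusted p under 0.05), and median centring gave 765 higher and 2533 lower.

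At 3.5 h the high dose raised the inflammatory genes as well. Csf3 reached log2 6.86 ± 0.49 (adjusted p = 0.000578), Il23a 6.02 ± 0.20 (adjusted p = 9.08e-05) and Ptgs2 5.93 ± 0.44 (adjusted p = 0.000616). Tnf stood at log2 5.82 ± 0.36, Il1a at 5.94 ± 0.41 and Il1b at 3.38 ± 0.46 (adjusted p from 0.000441 to 0.00338). The neutrophil chemokine gene Cxcl3 rose by log2 5.26 ± 1.36 (adjusted p = 0.0314), and Il10, the main anti-inflammatory cytokine of macrophages, by 4.91 ± 0.47 (adjusted p = 0.00125). Il17a, usually a product of lymphocytes, rose at least 5.01-fold from a control signal at background (adjusted p = 0.00139).

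Interferon-stimulated genes rose with Ifit2 at log2 4.15 ± 0.25, Isg15 at 3.47 ± 0.21 and Cxcl10 at 4.45 ± 0.48 (adjusted p from 0.000441 to 0.00164). Some immediate early genes joined them, with Dusp2 at log2 2.77 ± 0.26 and Junb at 2.30 ± 0.30 (adjusted p = 0.00109 and 0.00303), whereas Egr2 of the same list fell (-3.11 ± 0.39, adjusted p = 0.00266). Other risers were Hdc, which makes histamine (log2 4.52 ± 0.31), Inhba (5.01 ± 0.80), the cystine carrier Slc7a11 (3.82 ± 0.73), the matrix protease Mmp3 (3.96 ± 0.63) and the inflammasome sensor Nlrp3 (3.98 ± 0.34).

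The genes that fell the most included Rgs2 at log2 -4.77 ± 0.24, Cd300lb at -4.72 ± 0.28, Tmem86a at -4.67 ± 0.27 and Tifab at -4.66 ± 0.36 (adjusted p from 0.000441 to 0.000692), the last at -2.97 with the matched files under loess. Also lower were the fractalkine receptor Cx3cr1 (log2 -1.57 ± 0.29, adjusted p = 0.0103) and Cd209a (-1.64 ± 0.45, adjusted p = 0.0385). The cholesterol handling genes Abcg1 and Nceh1 fell (log2 -2.30 ± 0.29 and -2.35 ± 0.23), while other genes of their list rose. The cell cycle driver Ccnd1 fell as well (-3.16 ± 0.43, adjusted p = 0.0035). Angpt2 fell at least 5.27-fold to a signal at background (adjusted p = 0.000595). Arg1 was again not past the threshold (log2 -1.59 ± 1.13, adjusted p = 0.344, 0.00808 with the replicate block, and from 0.00808 to 0.887 over its alternatives).

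All 30 NF-kB targets were higher, also adjusted over the list alone, with a median log2 of 2.83 (adjusted p = 9.12e-23; adjusted p = 0.763 with an estimated correlation). Interferon-stimulated genes gave 34 of 36 higher (35 adjusted over the list alone). The list had a median log2 of 2.29 (adjusted p = 3.91e-24; adjusted p = 0.763 with an estimated correlation). For the cytokines the counts were 16 of 19 higher (18 higher and 1 lower adjusted over the list alone). Members had a median log2 of 3.39 (adjusted p = 1.25e-13, and 0.763 with an estimated correlation). Of the chemokines 13 of 25 were higher and 1 lower (14 and 2 adjusted over the list alone). The median log2 was 1.46 (adjusted p = 1.61e-05, and 0.783 with an estimated correlation).

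Smaller increases were found for immediate early genes (9 of 27 higher and 2 lower, 13 and 5 adjusted over the list alone, median log2 0.73, adjusted p = 0.0324, and 0.783 with an estimated correlation) and for antigen presentation (6 of 26 higher and 1 lower, 9 and 1 adjusted over the list alone, median log2 0.58 but -0.16 under median centring, adjusted p = 0.0104, and 0.824 with an estimated correlation). Dendritic cell markers gave 6 of 17 higher and 2 lower (8 and 2 adjusted over the list alone, median log2 0.97, adjusted p = 0.0304, and 0.763 with an estimated correlation), among them Zbtb46 at log2 3.31 ± 0.23, whose other probe moved the opposite way, Xcr1 at 2.12 ± 0.40 (1.25 with the matched files under loess) and Ccl17 at 1.57 ± 0.24. T and NK cell markers gave 3 of 21 higher, also adjusted over the list alone (median log2 0.57, adjusted p = 0.0351, and 0.763 with an estimated correlation), with Cd247 at log2 1.42 ± 0.23, Nkg7 at 1.12 ± 0.28 and Gzma at 0.82 ± 0.22. The last 2 were not past the threshold under median centring (0.40 and 0.28, adjusted p = 0.181 and 0.267). Median centring ended the calls of all 4 lists, with antigen presentation at an adjusted p of 0.442, immediate early genes at a median of 0.00 (adjusted p = 0.255), T and NK cells at 0.00 (adjusted p = 0.262) and dendritic cells at 0.24 (adjusted p = 0.0699). Without the background filter the last 3 were not past the threshold either (adjusted p = 0.1, 0.13 and 0.115), nor were immediate early genes under the strict filter (adjusted p = 0.106).

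On the falling side macrophage identity gave 11 of 20 lower and 1 higher (12 and 1 adjusted over the list alone, median log2 -1.01, adjusted p = 0.0146, and 0.783 with an estimated correlation). The cell cycle list gave 12 of 36 lower and 3 higher (15 and 3 adjusted over the list alone, median log2 -0.91, or -0.75 with members at background held at their bound, adjusted p = 0.00895, and 0.898 with an estimated correlation). Cholesterol efflux and lipid storage gave 10 of 25 lower and 3 higher (11 and 4 adjusted over the list alone, median log2 -0.73, adjusted p = 0.0468, and 0.77 with an estimated correlation).

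Ribosomal proteins had 5 of 34 lower (4 adjusted over the list alone) and a median log2 of -0.50 (adjusted p = 0.00017, and 0.893 with an estimated correlation), with Rps6 at -1.20 ± 0.28 and Rpl13 at -1.19 ± 0.23. Nuclear genes of the respiratory chain had 5 of 25 lower (6 adjusted over the list alone) and a median log2 of -0.46 (adjusted p = 0.0247, and 0.898 with an estimated correlation), with Sdhb at -1.12 ± 0.20. The matched files under loess ended the calls of macrophage identity (-0.86, adjusted p = 0.0616), cholesterol efflux (-0.40, adjusted p = 0.0779) and the respiratory chain (-0.38, adjusted p = 0.0824). Processed signals ended that of cholesterol efflux (-0.57, adjusted p = 0.0724).

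The high dose at 3.5 h changed 5724 genes, 2661 higher and 3063 lower. Leaving out replicate 1 gave 901 and leaving out replicate 2 gave 2442, and 38 and 63 of 113 named calls remained past the threshold. With the scanner files as recorded limma called 0 genes (2884 at an unadjusted p under 0.05), and median centring gave 2905 higher and 8948 lower.

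After 48 h at the low dose the named genes that rose were mostly interferon-stimulated. Gbp2b, a guanylate-binding protein gene of antimicrobial defence, rose by log2 4.92 ± 0.42 (adjusted p = 0.0136) and Ifit2 by 4.55 ± 0.25 (adjusted p = 0.00411). Ifit3 rose by log2 3.53 ± 0.23, Ifit1 by 3.16 ± 0.24 and Ifi44 by 3.20 ± 0.24 (adjusted p from 0.00809 to 0.00997). The immunity-related GTPase gene Tgtp1 rose by log2 3.78 ± 0.35, Slfn1 by 3.81 ± 0.39, the antiviral sensor gene Oas3 by 3.46 ± 0.43 and the chemokine gene Ccl5 by 3.16 ± 0.29 (adjusted p from 0.0152 to 0.0482). With the matched files under loess Ifit2 was at log2 2.34 and Ifit1 at 2.05, still past the threshold, whereas Slfn1 (2.27, adjusted p = 0.0812), Tgtp1 (1.73, adjusted p = 0.38) and Oas3 (1.87, adjusted p = 0.343) were not.

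Tnf was no longer past the threshold (log2 0.87 ± 0.36, adjusted p = 0.474). Il1b was at log2 2.36 ± 0.46 (adjusted p = 0.122, 0.04 with the replicate block, and from 0.04 to 0.68 over its alternatives), Cd209a at -2.69 ± 0.45 (adjusted p = 0.0905, 0.0256 with the replicate block, and from 0.0256 to 0.623 over its alternatives). With the matched files under loess the Cd209a signals lay closer together, at a mean log2 of 9.02 with LECT2 and 10.365 in the control. Arg1 was at log2 1.35 ± 1.13 (adjusted p = 0.751), and at -0.31 without replicate 1. The 5 genes that fell had a LECT2 signal at background: Prl2c5 was at least 1.49-fold lower (adjusted p = 0.0152), Fam13c 1.30-fold, Mtus2 1.34-fold and Crb2 1.17-fold (adjusted p from 0.0219 to 0.0489), while Otogl was at background in both channels and has no fold (adjusted p = 0.0378). None of the 5 remained past the threshold with the matched scanner files under normexp and loess.

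Of the 36 interferon-stimulated genes 12 were higher and 0 lower (34 higher adjusted over the list alone). Their median log2 was 1.79 (adjusted p = 7.37e-50; adjusted p = 0.763 with an estimated correlation). Antigen presentation had 0 of 26 past the threshold over all genes and 16 higher adjusted over the list alone, median log2 1.15 (adjusted p = 5.93e-18; adjusted p = 0.763 with an estimated correlation). Cytokines (2 of 19 higher adjusted over the list alone, median log2 0.66, or 0.64 with members at background held at their bound, adjusted p = 3.08e-06, and 0.783 with an estimated correlation) and NF-kB targets (1 of 30 higher adjusted over the list alone, median log2 0.32 but -0.21 and adjusted p = 0.911 under median centring, adjusted p = 0.000711, and 0.893 with an estimated correlation) had 0 genes past the threshold over all genes. Chemokines had 1 of 25 higher (5 adjusted over the list alone). The group had a median log2 of 0.66, or 0.48 with members at background held at their bound (adjusted p = 9.7e-06, and 0.783 with an estimated correlation). T and NK cell markers had 0 of 21 past the threshold (4 higher and 1 lower adjusted over the list alone, median log2 0.31, adjusted p = 0.000802, and 0.763 with an estimated correlation).

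Lower as groups, with 0 genes past the threshold over all genes in each, were the cell cycle (0 of 36 adjusted over the list alone, median log2 -0.54, adjusted p = 2.9e-06, and 0.783 with an estimated correlation) and cholesterol synthesis (0 of 25 adjusted over the list alone, median log2 -0.26, adjusted p = 0.0161, and 0.783 with an estimated correlation). Mesothelium and fibroblast markers were lower in 5 of 24 genes adjusted over the list alone (median log2 -0.74, or -0.70 with members at background held at their bound, adjusted p = 1.61e-05, and 0.763 with an estimated correlation).

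The low dose at 48 h changed 45 genes, 40 higher and 5 lower, and 97 with the replicate block, the 45 among them. A trended robust variance gave 0 (2411 at an unadjusted p under 0.05), no filter 19, the strict filter 89 and centred columns 29. Leaving out replicate 1 gave 0 genes by limma (1817 at an unadjusted p under 0.05) and leaving out replicate 2 gave 5, and of the 15 named calls 0 and 1 remained. With the scanner files as recorded 50 genes passed, 11 of them among the 45, and median centring gave 22 higher and 44 lower.

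At 48 h the high dose raised cytokines of T cell immunity and interferon-stimulated genes. Il17a rose by a fitted log2 8.23 ± 0.51 (adjusted p = 0.00154), with a control signal (log2 6.36) no brighter than that of Ifng (6.51), which was at background. With the matched files under loess Il17a stood at log2 5.32. Iltifb, a gene of the interleukin 22 family, rose at least 21.2-fold (adjusted p = 0.00177) and Ifng at least 7.47-fold (adjusted p = 0.00601). Il12a, a subunit of the cytokine that induces interferon gamma, rose at least 3.82-fold (adjusted p = 0.00317). Il1b rose by log2 4.70 ± 0.46 and Il6 by 3.24 ± 0.44 (adjusted p = 0.00332 and 0.00882), whereas Tnf was not past the threshold (log2 0.50 ± 0.36, adjusted p = 0.399), and its sign reversed to log2 -0.23 under median centring and to -0.06 without replicate 1.

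Interferon-stimulated genes rose, with Ifit1 at log2 4.75 ± 0.24, Gbp2b at 5.27 ± 0.42 and Gbp3 at 4.69 ± 0.27 (adjusted p from 0.00141 to 0.00228). The transporter of antigen peptides Tap1 rose by log2 2.41 ± 0.28 and the immunoproteasome subunit Psmb8 by 2.42 ± 0.29 (adjusted p = 0.00556 and 0.00574). Lcn2 rose by log2 3.83 ± 0.43, the scavenger receptor Marco by 3.01 ± 0.77 and the acyl-CoA synthetase Acsl1 by 5.13 ± 0.48 (adjusted p from 0.00319 to 0.0469). Marco stood at log2 4.48 and 1.55 on its 2 arrays, and without either it was not past the threshold. Genes of low oxygen and glycolysis rose, among them Bnip3 at log2 3.24 ± 0.48, Egln3 at 2.80 ± 0.46 and Pgk1 at 2.42 ± 0.51 (adjusted p from 0.0108 to 0.0277), the last at 1.58 without replicate 1.

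Several genes known from resident macrophages fell, while the lists of large peritoneal macrophages (3 of 20 higher and 5 lower, adjusted p = 0.0928) and of alternative activation (2 of 24 higher and 6 lower, adjusted p = 0.528) were not past the threshold. The genes that fell included Cd209a (log2 -4.87 ± 0.45, adjusted p = 0.00319, and -2.95 with the matched files under loess), the complement receptor Vsig4 (-4.53 ± 0.50, adjusted p = 0.00518) and the complement components C1qa (-2.93 ± 0.26) and C1qb (-3.31 ± 0.36, adjusted p = 0.00319 and 0.00479). Alox15, a lipoxygenase of resident peritoneal macrophages, fell at least 7.67-fold (adjusted p = 0.00329) and the lectin gene Cd209b at least 3.46-fold (adjusted p = 0.00331). The mannose receptor Mrc1 fell less (log2 -1.83 ± 0.37, adjusted p = 0.0245). Cholesterol synthesis fell with Fdft1 at log2 -2.23 ± 0.24, its regulator Srebf2 at -1.65 ± 0.30 and Insig1 at -1.62 ± 0.29 (adjusted p from 0.00492 to 0.0186). Cenpa, needed for cell division, fell (log2 -3.07 ± 0.24), whereas Mki67 rose by 2.52 ± 0.37. Arg1 was not past the threshold (log2 1.76 ± 1.13, adjusted p = 0.342, 0.0111 with the replicate block, and from 0.0111 to 0.983 over its alternatives).

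**Figure D2:**
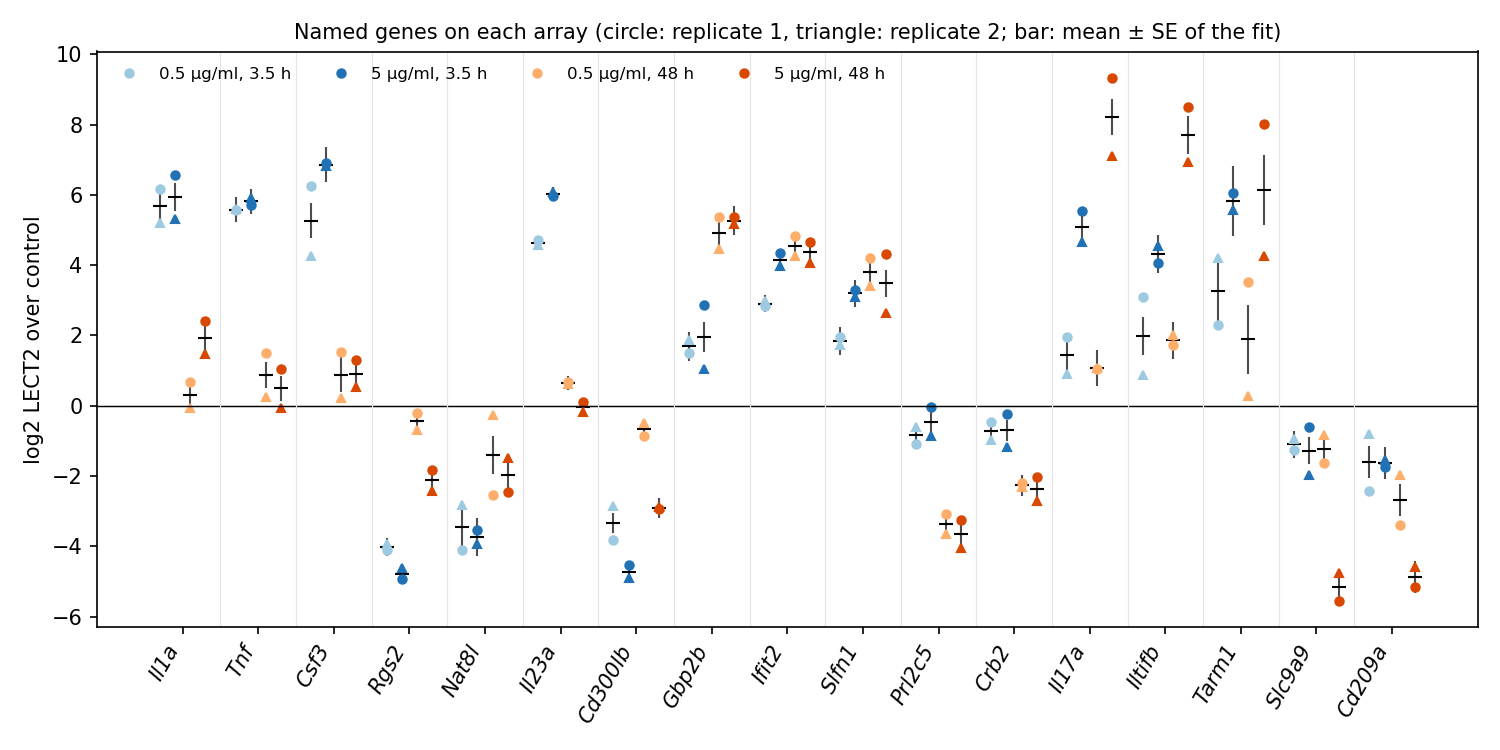
Log2 change, LECT2 over control (vertical axis), of 17 named genes in the 4 groups, with replicate 1 as a circle, replicate 2 as a triangle and a bar for the mean ± SE (n = 2). Tnf stood at 5.58 and 5.82 at 3.5 h and at 0.87 and 0.50 at 48 h, with its sign reversed under median centring for the high dose at 48 h, while Ifit2 was positive in all 4 groups.

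Of the interferon-stimulated genes 31 of 36 were higher (35 adjusted over the list alone). The list had a median log2 of 1.91 (adjusted p = 1.53e-28; adjusted p = 0.763 with an estimated correlation). NF-kB targets gave 15 of 30 higher (18 adjusted over the list alone). Members had a median log2 of 1.14 (adjusted p = 1.56e-09, and 0.783 with an estimated correlation). Glycolysis and hypoxia gave 12 of 30 higher (16 adjusted over the list alone). The median log2 was 1.06 (adjusted p = 7e-07, and 0.783 with an estimated correlation). Antigen presentation gave 10 of 26 higher (12 adjusted over the list alone). Its median log2 was 0.82 but -0.02 under median centring (adjusted p = 7.19e-05, and 0.783 with an estimated correlation). Cytokines had 7 of 19 higher and 1 lower (9 and 2 adjusted over the list alone). The group had a median log2 of 1.01 (adjusted p = 0.000454, and 0.824 with an estimated correlation). Chemokines had 6 of 25 higher and 1 lower (7 and 4 adjusted over the list alone). The list had a median log2 of 0.61 (adjusted p = 0.0244, and 0.945 with an estimated correlation).

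Cholesterol synthesis was lower in 8 of 25 genes (14 adjusted over the list alone). Members had a median log2 of -0.87 (adjusted p = 2.43e-05, and 0.783 with an estimated correlation). The cell cycle had 10 of 36 lower and 1 higher (18 and 2 adjusted over the list alone). The median log2 was -0.94, or -0.92 with members at their bound (adjusted p = 9.7e-06, and 0.783 with an estimated correlation). Macrophage identity had 8 of 20 lower and 1 higher (10 and 1 adjusted over the list alone). Its median log2 was -0.77 (adjusted p = 0.00412, and 0.783 with an estimated correlation). Mesothelium and fibroblast markers had 5 of 24 lower (10 adjusted over the list alone). The group had a median log2 of -0.89, or -0.79 with members at their bound (adjusted p = 0.000664, and 0.783 with an estimated correlation), with Pdgfra at log2 -3.51 ± 0.27 (adjusted p = 0.052 for the list under median centring). T and NK cell markers had 2 of 21 higher, Cd3g at log2 1.30 ± 0.25 and Gzma at 1.21 ± 0.22 (0.71 and 0.56 with the matched files under loess, adjusted p = 0.0455 and 0.0973), and 1 lower, Klrb1c at least 1.54-fold, and the list was not past the threshold (median log2 0.28, adjusted p = 0.345).

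In the high dose at 48 h limma called 2933 genes, 1126 higher and 1807 lower, and 1689 without the background filter. Leaving out replicate 1 gave 14 genes and leaving out replicate 2 gave 57, and of the 98 named calls 9 and 21 remained past the threshold. Ifng, Cd209a and Alox15 rested on both arrays: without either one no adjusted p stayed under 0.05. With the scanner files as recorded 1 gene was called, and median centring gave 1836 higher and 6831 lower.

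**Figure D3:**
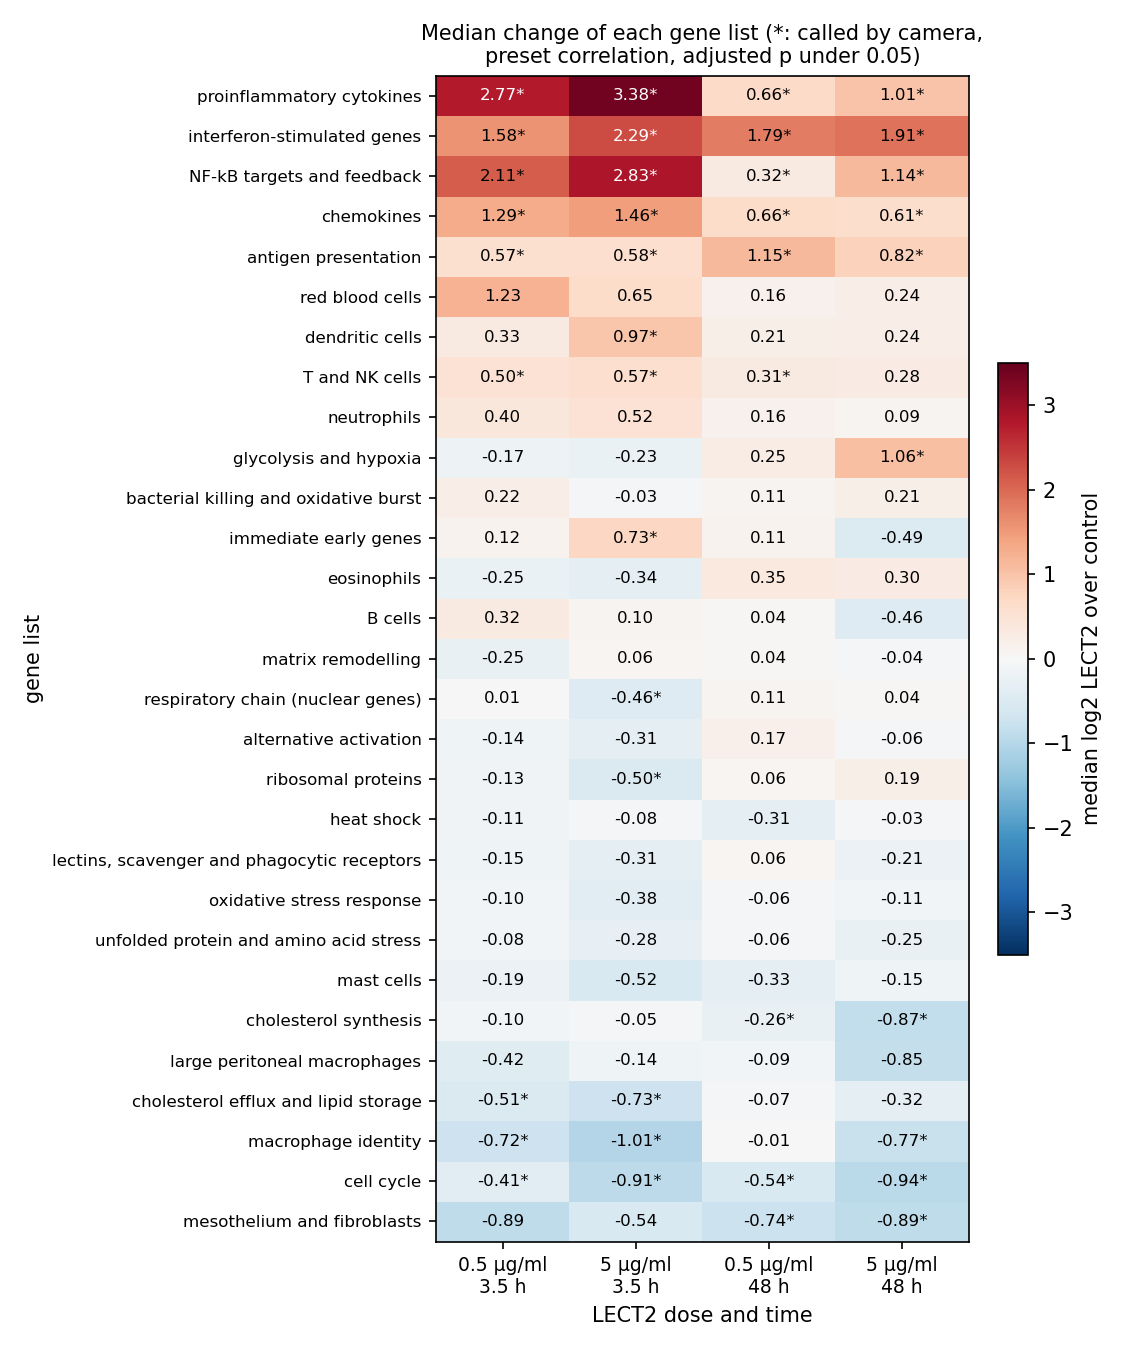
Median log2 change, LECT2 over control (colour), of 29 gene lists (vertical axis) in the 4 groups (horizontal axis), where a star marks a list past an adjusted p of 0.05 with the preset correlation. Interferon-stimulated genes had medians of 1.58 and 2.29 at 3.5 h and 1.79 and 1.91 at 48 h, and 0 of the 83 list calls over all comparisons held with an estimated correlation.

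Most genes called at the low dose were also called at the high dose. At 3.5 h 627 of the 718 genes higher at the low dose were also higher at the high dose, against 73.07 for independent lists of these sizes, 3 were lower, and 505 of 561 lower genes were shared, against 65.72. At 48 h 38 of 40 higher genes and 5 of 5 lower genes were shared, against 1.723 and 0.3455. Across genes, which are not independent replicates, the changes at the 2 doses correlated at r = 0.72 at 3.5 h and 0.589 at 48 h. Controls shared between doses give r = 0.50 in simulations without an effect, and the covariances were 0.453 and 0.235 against a simulated 0.0584. The simulation held no dye effect shared by all arrays. Single arrays that differed in time, dose and replicate still covaried at a median of 0.1645, so the simulated value may be too low a baseline.

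Tested directly, the difference between the high and low dose passed for 0 genes by limma at 3.5 h (2048 at an unadjusted p under 0.05, smallest adjusted p = 0.205) and for 0 genes at 48 h (2738, smallest adjusted p = 0.0928). The replicate block, with a single replicate term for both times, gave 0 genes at 48 h as well (3085, smallest adjusted p = 0.0821 by limma). Among the largest differences were Il19 at 3.5 h (log2 4.77 ± 0.50, adjusted p = 0.205) and at 48 h Il17a (log2 7.16 ± 0.72, adjusted p = 0.0928), a fitted value since a channel was at background. Under median centring both passed (3.07 and 4.48, adjusted p = 0.0196 and 0.0266). At 48 h Tmem176a (log2 -3.05 ± 0.35, adjusted p = 0.108) and C1qa (log2 -2.92 ± 0.37, adjusted p = 0.114) were lower at the high dose without passing. Leaving out replicate 2 of the low dose at 3.5 h raised the early count to 436, and the matched files under loess gave 8 and 21 genes. In simulated data with a log2 difference of 2 at 48 h the test recovered 29.4% of the changed genes.

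With the preset correlation alone some lists passed for a difference by dose, each with 0 genes past the threshold over all genes. None of them held with an estimated correlation. At 3.5 h the high dose gave more of the interferon-stimulated genes (median difference of log2 0.81, adjusted p = 1.02e-12, and 0.783 with an estimated correlation), cytokines (1.11, adjusted p = 1.55e-05, and 0.783 with an estimated correlation, 3 higher adjusted over the list alone), NF-kB targets (0.31, adjusted p = 0.000309, and 0.871 with an estimated correlation), immediate early genes (0.47, adjusted p = 0.00129, and 0.783 with an estimated correlation, 1 higher adjusted over the list alone) and dendritic cell markers (0.48, adjusted p = 0.00895, and 0.763 with an estimated correlation). It gave less of the ribosomal proteins (-0.39, adjusted p = 0.000291, and 0.893 with an estimated correlation) and of the respiratory chain (-0.36, adjusted p = 0.00112, and 0.824 with an estimated correlation).

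At 48 h the high dose gave more of the NF-kB targets (0.87, adjusted p = 6.14e-08, and 0.783 with an estimated correlation, 4 higher adjusted over the list alone), glycolysis and hypoxia (0.67, adjusted p = 6.43e-06, and 0.783 with an estimated correlation, 3 higher adjusted over the list alone) and interferon-stimulated genes (0.34, adjusted p = 0.000642, and 0.893 with an estimated correlation). Less expressed were macrophage identity (-0.71, adjusted p = 9.7e-06, and 0.77 with an estimated correlation, 6 lower adjusted over the list alone) and cholesterol synthesis (-0.59, adjusted p = 0.000377, and 0.783 with an estimated correlation). Alternative activation (-0.39, adjusted p = 0.0316, and 0.783 with an estimated correlation, 2 lower adjusted over the list alone) and the cell cycle (-0.40, adjusted p = 0.0409, and 0.946 with an estimated correlation, 1 lower adjusted over the list alone) were also lower. The call of alternative activation ended under median centring (-0.17, adjusted p = 0.443), the strict filter (-0.29, adjusted p = 0.137) and the matched files under loess (-0.11, adjusted p = 0.276). That of the cell cycle ended under the strict filter (adjusted p = 0.177).

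Early and late responses shared part of their genes at the high dose. Of 2661 genes higher at 3.5 h and 1126 higher at 48 h, 447 were in both, against 114.6 for independent lists, and 56 of the early higher genes were lower at 48 h. Of 3063 lower early and 1807 lower late, 511 were in both, against 211.7, and 85 had turned higher. At the low dose 23 genes were higher at both times, against 1.098, and 0 lower at both. Independent lists may be too low a baseline, since a dye effect equal on every array would add shared genes. Ratios of single arrays that differed in time, dose and replicate correlated at a median r of 0.2553. Among named genes Ifit2, Il1b, Acod1 and Traf1 were higher at both times with the high dose, and Egr2, Ccnd1, Pdgfra and Cd209a were lower at both.

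Tested directly at the low dose, the effect at 48 h was lower than that at 3.5 h for Tnf (a difference of log2 -4.71 ± 0.51), Il1a (-5.38 ± 0.58) and the inflammatory brake Tnip1 (-3.15 ± 0.29) (adjusted p from 0.022 to 0.0328). It was higher for Rgs2 by log2 3.58 ± 0.35 and Vsir by 2.79 ± 0.33 (adjusted p = 0.0275 and 0.0449), genes that had fallen early. With the replicate block Vsir was at an adjusted p of 0.053, and its alternatives ranged from 0.00636 to 0.277. In all 26 genes differed, 4 with a higher effect at 48 h and 22 with a lower one. No filter, a trended robust variance and a fit of only the groups compared each gave 0 (3815, 2572 and 2699 at an unadjusted p under 0.05), while the matched files under loess gave 231. Leaving out replicate 2 of the early low dose gave 240 genes, leaving out replicate 2 of the late low dose gave 2, and leaving out either replicate 1 gave 0 by limma (2125 and 2107 at an unadjusted p under 0.05).

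At the high dose the effect was lower late for some inflammatory genes but not for Il1b (log2 3.38 early and 4.70 late), Acod1 (3.64 and 3.61) or Traf1 (3.37 and 3.47). In the control channel Il1b and Acod1 were lower at 48 h (log2 -2.26 ± 0.36 and -2.04 ± 0.30), which alone would raise their late ratios. Tnf was lower there too (-1.58 ± 0.22). The effect on Tnf differed by log2 -5.32 ± 0.51, on Csf3 by -5.94 ± 0.70, on Il27 by -5.64 ± 0.30 and on Il23a by a fitted -6.05 ± 0.28 (adjusted p from 0.00119 to 0.0119). Immediate early genes followed with Dusp2 at log2 -3.30 ± 0.36 and Ier2 at -3.25 ± 0.41. The effect was higher late for Tgfbi, a matrix protein gene, by log2 5.91 ± 0.87, Gbp8 by 5.57 ± 1.04, the hypoxia genes Bnip3 by 3.76 ± 0.68 and Egln3 by 3.16 ± 0.64, and Rps6 by 1.92 ± 0.40 (adjusted p from 0.0164 to 0.0333). Rps6 had fallen at 3.5 h, so its difference need not be a rise at 48 h. In all 2170 genes differed, 1181 with a higher effect at 48 h and 989 with a lower one, against 940 without the background filter and 4596 with the matched files under loess. Leaving out replicate 2 of the early high dose gave 0 by limma (6266 at an unadjusted p under 0.05), leaving out any other single array of the comparison gave 2, and with the scanner files as recorded 0 genes passed at either dose (511 and 268 at an unadjusted p under 0.05).

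Cytokines and NF-kB targets differed between times at both doses. NF-kB targets had a median difference of log2 -1.69 at the low dose (3 of 30 lower, 20 adjusted over the list alone, adjusted p = 2.39e-28, and 0.763 with an estimated correlation) and -1.35 at the high dose (12 lower, 18 adjusted over the list alone, adjusted p = 1.47e-09, and 0.783 with an estimated correlation). Cytokines had -1.96 at the low dose (4 of 19 lower, 9 adjusted over the list alone, adjusted p = 8.37e-12, and 0.77 with an estimated correlation) and -2.54 at the high dose (10 lower, 11 lower and 1 higher adjusted over the list alone, adjusted p = 9.18e-06, and 0.783 with an estimated correlation). Glycolysis and hypoxia rose late at the high dose (5 of 30 higher, 8 adjusted over the list alone, median difference of log2 0.82, adjusted p = 0.000237, and 0.843 with an estimated correlation). Time coincided with the slide under the matched scanner files, so a slide effect on the ratios and the time cannot be told apart. Time also coincided with how the columns relate to the files, since only the 48 h columns equal the software's ratio. The matched files under loess were processed alike at both times.

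The control channel alone was compared between 48 h and 3.5 h, with the scanner files matched to the table's columns. Each slide then holds a single time, so changes given here as a rise or fall cannot be told apart from a slide effect. Interferon-stimulated genes were lower at 48 h without LECT2, with Ifit1 at log2 -2.63 ± 0.19, Oasl1 at -2.74 ± 0.18 and Ifi27l2a at -3.11 ± 0.17 (adjusted p = 0.03 for each). Chemokine genes fell with Cxcl10 at log2 -2.25 ± 0.19, Ccl5 at -2.21 ± 0.17 and Cxcl9 at -2.03 ± 0.21 (adjusted p = 0.03 for each), and antigen presentation with H2-DMa at -2.14 ± 0.32 and H2-Ab1 at -1.55 ± 0.29 (adjusted p = 0.0339 and 0.0442). Il1b fell (log2 -2.26 ± 0.36, adjusted p = 0.0355), as did Tnf (log2 -1.58 ± 0.22, adjusted p = 0.0315). For genes that fell here, the lower control alone would raise the ratio of LECT2 to control at 48 h. The transcription factor Maf rose by log2 2.84 ± 0.21, the cholesterol synthesis genes Idi1 and Sc5d by 2.63 ± 0.37 and 2.45 ± 0.41, and the chaperones Hspa5 and Dnaja1 by 2.19 ± 0.37 and 2.01 ± 0.19 (adjusted p from 0.03 to 0.038). The mast cell markers Cma1 and Cpa3 fell (log2 -3.87 ± 0.57 and -3.42 ± 0.62, adjusted p = 0.0336 and 0.042).

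As groups in the control channel, interferon-stimulated genes had 12 of 36 lower and 1 higher (20 and 1 adjusted over the list alone). The list had a median log2 of -0.79 (adjusted p = 1.35e-09, and 0.763 with an estimated correlation). Antigen presentation had 9 of 24 lower (17 lower and 1 higher adjusted over the list alone). Members had a median log2 of -0.86 (adjusted p = 2.5e-07, and 0.783 with an estimated correlation). Chemokines had 7 of 25 lower (10 adjusted over the list alone). The median log2 was -0.58 (adjusted p = 9.18e-06, and 0.783 with an estimated correlation). In all limma called 1369 genes, 733 higher and 636 lower at 48 h, in a test that made 27 false of 185 calls on simulated data. The low-dose arrays alone gave 0 (5132 at an unadjusted p under 0.05), no filter 346 and processed signals 2515. Leaving out replicate 2 of the control at 3.5 h gave 2649 genes, and leaving out replicate 1 at 3.5 h or replicate 1 or 2 at 48 h gave 0 (4462, 3954 and 5409 at an unadjusted p under 0.05). With the scanner files as recorded the count was 0 (33 at an unadjusted p under 0.05), and because all arrays of a time shared a slide under the matched files, time and slide cannot be told apart.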

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

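All tests of explanations in this part were chosen after the results they measure were seen, while the tests of the time differences themselves were planned. Every difference between times given here is the effect at 48 h minus the effect at 3.5 h, taken up because a test of the difference between the 2 times passed.

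At the low dose 26 genes differed between times. Negative differences were found for Il1a at log2 -5.38 ± 0.58 (adjusted p = 0.0328), Tnf at -4.71 ± 0.51, Tnip1 at -3.15 ± 0.29 and Tnfaip2 at -2.97 ± 0.31. Il23a stood at a fitted -3.99 ± 0.28, since a channel was at background. Tmem18 (-5.10 ± 0.46) and Riok2 (-4.64 ± 0.39) were negative as well. Positive differences were found for Rgs2 at log2 3.58 ± 0.35 (adjusted p = 0.0275), Eepd1 at 3.02 ± 0.31 and Vsir at 2.79 ± 0.33. The replicate block moved Vsir to an adjusted p of 0.053 (from 0.00636 to 0.277 over its alternatives). Without replicate 2 of the early low dose all 13 named calls remained, and without any other array of the comparison 0 of the 13 did.

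At the high dose 2170 genes differed. Lower late were Il23a at a fitted log2 -6.05 ± 0.28 (adjusted p = 0.00119), Il19 at a fitted -6.22 ± 0.50, Csf3 at -5.94 ± 0.70, Il27 at -5.64 ± 0.30 and Tnf at -5.32 ± 0.51. The NF-kB feedback genes Tnfaip2 (-3.40 ± 0.31) and Nfkbiz (-3.28 ± 0.54) and the immediate early genes Dusp2 (-3.30 ± 0.36) and Ier2 (-3.25 ± 0.41) followed, as did the fibroblast markers Postn (a fitted -2.50 ± 0.39) and Pdgfra (-2.10 ± 0.38). The effect was higher late for Tgfbi at log2 5.91 ± 0.87 (adjusted p = 0.0164), Gbp8 at 5.57 ± 1.04, Mtus1 at 4.98 ± 0.47, Htr2b at a fitted 4.83 ± 0.43 and Tmem86a at 4.61 ± 0.38. With the matched files under loess Gbp8 was at 3.37, Mtus1 at 3.14, Htr2b at 3.01 and Pdgfra at -1.32, all past the threshold, and Postn at -0.85 was not (adjusted p = 0.0778). Differences were positive for the hypoxia genes Bnip3 at log2 3.76 ± 0.68 and Egln3 at 3.16 ± 0.64, and for Rpl5 at 2.02 ± 0.35, Rps6 at 1.92 ± 0.40 and Sdhb at 1.53 ± 0.29. Tmem86a, Rps6 and Sdhb had fallen at 3.5 h, so their positive differences need not be a rise at 48 h. Bnip3 and Egln3 were higher than control at 48 h. Of 67 named calls 0 remained without replicate 2 of the early high dose and 2 without each other array of the comparison.

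As lists, NF-kB targets (median difference of log2 -1.69 at the low dose and -1.35 at the high dose) and proinflammatory cytokines (-1.96 and -2.54) passed at both doses with the preset correlation. With an estimated correlation none did (adjusted p = 0.763 and 0.783, and 0.77 and 0.783). At the low dose chemokines (-0.56, adjusted p = 0.00872), macrophage identity (0.70, adjusted p = 0.000377), antigen presentation (0.54, adjusted p = 0.00273), glycolysis and hypoxia (0.55, adjusted p = 0.0224) and cholesterol efflux (0.46, adjusted p = 0.0405) also differed. None of these 5 held with an estimated correlation (adjusted p = 0.893, 0.783, 0.783, 0.946 and 0.77). Interferon-stimulated genes had a higher ratio to control late at the low dose (0.51, adjusted p = 0.0155, and 0.946 with an estimated correlation). This direction reversed to -0.13 with the matched files under loess and to -0.11 under median centring. In the control channel this list was lower at 48 h, which alone would raise the late ratio. The call of interferon-stimulated genes ended with processed signals (adjusted p = 0.0632), and that of chemokines without the background filter (adjusted p = 0.0751). At the high dose the others were glycolysis and hypoxia (0.82, adjusted p = 0.000237), ribosomal proteins (0.63, adjusted p = 0.000127), the respiratory chain (0.42, adjusted p = 0.0146), immediate early genes (-0.67, adjusted p = 0.0102) and mesothelium and fibroblasts (-0.52, adjusted p = 0.0371). With an estimated correlation none of these 5 held (adjusted p = 0.843, 0.893, 0.893, 0.783 and 0.809). The call of mesothelium and fibroblasts also ended with the matched files under loess (adjusted p = 0.202), processed signals (adjusted p = 0.0891) and the strict filter (adjusted p = 0.148). Over all genes 2 of 34 ribosomal proteins and 1 of 25 respiratory chain genes were higher (10 and 1 adjusted over the list alone), and 7 of 27 immediate early genes and 2 of 24 mesothelium and fibroblast markers lower (10 and 2 adjusted over the list alone). The lists that passed at the low dose alone had 0 members past the threshold over all genes, and adjusted over the list alone 4 interferon-stimulated genes were higher and 1 lower. Time and slide cannot be told apart under the matched files, because each slide holds a single time, so a slide effect on the ratios stays open beside an effect of time. The 3.5 h and 48 h columns also differ in how closely they follow the scanner files, which coincides with time in the same way.

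The early inflammatory response at the high dose was set against 3 technical explanations over 85 measured cytokines, NF-kB targets and interferon-stimulated genes. A dye effect of single probes is argued against by the other probes of the 80 called members, of which 19 of 19 (100%) were also higher. A dye effect equal on every array would cancel between doses, yet the median difference of the high against the low dose was log2 0.632 over all 85 members, and 62 of them (72.9%) were higher at the high dose in both replicates, which is consistent with a response that grows with the dose. Endotoxin carried by the recombinant protein cannot be told apart from LECT2 itself, since 0 of the 8 arrays had heat-treated protein or an endotoxin inhibitor.

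The T cell cytokines at the high dose and 48 h (Il17a, Iltifb and Ifng) were a further pattern. More T and NK cells of every kind, each with the same expression, are argued against as the whole cause by their markers. Their median was log2 0.28 over 21 genes with an upper quartile of 0.677, while the smallest change of the 3 cytokines was log2 2.90 at its bound. Some markers did rise, Cd3g by log2 1.30 (adjusted p = 0.0216) and Gzma by 1.21 (adjusted p = 0.0191, and 0.0973 with the matched files under loess). Not past the threshold were Cd3d at 1.00 (adjusted p = 0.0801) and Gzmb at 3.25 (4.98 and 1.52 on its 2 arrays, adjusted p = 0.0648). A smaller rise in T cells, or growth of a single kind, stays open. At the high dose and 3.5 h Il17a and Iltifb were already at a fitted log2 5.09 and 4.31 (adjusted p = 0.00139 and 0.00263 by limma). Ratios inflated by a control signal near background are argued against as the whole cause by the bound, which still gave at least 7.47-fold for the smallest. The size of the rise stays uncertain, with fitted folds of 65.5 for Ifng and 209.6 for Iltifb against bounds of 7.47 and 21.25. Whether this response grows with the dose cannot be told: the 3 genes were picked for their rise at the high dose, and none differed between doses past the threshold (smallest difference log2 2.70 for Ifng, adjusted p = 0.432, and from 0.0928 for the 3). Under median centring Il17a did differ (log2 4.48, adjusted p = 0.0266). Activation of T cells already present in the cultures also stays open, since no array measured sorted cells.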

How the results depend on the processing

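The runs on the scanner files, matched or as recorded, and the centred columns were chosen after the data were seen, and the other settings were planned. Counts below are genes at an adjusted p under 0.05 by limma, against 1279, 5724, 45 and 2933 for the low and high dose at 3.5 h and at 48 h, 0 and 0 for the dose differences, 26 and 2170 for the time differences and 1369 for the control channel.

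Taken as recorded, the scanner files gave 0 genes with normexp and loess and 24 with processed signals for the low dose at 3.5 h, and 0 and 0 for the high dose. For the high dose at 48 h they gave 1 and 0, for the time differences 0 in all 4 runs, and for the control channel 0. The low dose at 48 h gave 50 and 47, 11 of the 45 genes among them in each run. At an unadjusted p under 0.05 limma counted 952 genes (low dose, 3.5 h) and 2884 and 3050 (high dose, 3.5 h). The high dose at 48 h gave 2869 with processed signals, and the time differences gave 511 and 652 (low dose) and 268 and 289 (high dose).

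With the files matched to the columns, normexp and loess gave 2374 genes for the low dose at 3.5 h, 8 and 21 for the dose differences and 231 and 4596 for the time differences. Of the 1279, 5724, 45 and 2933 genes, 1048, 5327, 21 and 2227 were among those called with these files. Aquantile leaves ratios within an array as they are, so its equal counts (2374, 8, 21, 231 and 4596) test nothing. Keeping outlier spots gave 2377, 8, 9, 230 and 4590 in the same comparisons. Without background correction the counts were 2422 (low dose, 3.5 h), 8718 (high dose, 3.5 h), 10 (dose difference, 3.5 h), and 184 and 4876 (time differences).

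On the matched files median centring in place of loess gave 3298, 11853 and 8667 genes for the low and high dose at 3.5 h and the high dose at 48 h, 3 and 9 for the dose differences and 111 for the time difference at the low dose. The share of higher genes was then 23.2%, 24.5%, 33.3% and 21.2% in the 4 groups, against 56.1%, 46.5%, 88.9% and 38.4%, and 55.6%, 46.5%, 89.7% and 41.9% when the columns of the table itself were centred. For the time difference at the low dose the share of higher genes was 27.3% with loess and 26.6% without background correction, against 15.4%. Median centring reversed Otogl at the low dose and 48 h to log2 0.088 and Tnf at the high dose and 48 h to -0.23. Interferon-stimulated genes reversed between times at the low dose, to -0.11 under median centring and -0.13 with loess.

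Without the background filter the counts were 733 (low dose, 3.5 h), 19 (low dose, 48 h), 1689 (high dose, 48 h), 0 (time, low dose, 3815 at an unadjusted p under 0.05) and 940 (time, high dose). The strict filter gave 89 for the low dose at 48 h and 53 for the time difference at the low dose. Centred columns gave 29 for the low dose at 48 h. A trended robust variance gave 753 for the low dose at 3.5 h, 0 for the low dose at 48 h (2411 at an unadjusted p under 0.05) and 0 for the time difference at the low dose (2572). Fitting only the groups compared gave 0 for the low dose at 3.5 h (4665 at an unadjusted p under 0.05) and 0 for the time difference at the low dose (2699). A 2-fold change on both arrays with no test held for 3460 (high dose, 3.5 h), 570 (low dose, 48 h), 757 and 1381 (dose differences) and 1412 and 3737 genes (time differences).

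The replicate block raised the low dose at 48 h to 97 genes and left the other counts within 1.5 times. Among 473 named values it ended 10 calls and made 6, and it changed no other named call.

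For the control channel processed signals with quantile scaling gave 2515, median centring then Aquantile 2092, no filter 346, the strict filter 2230 and the trended variance 2437. The low-dose arrays alone gave 0 (5132 at an unadjusted p under 0.05).

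Leaving out 1 array gave between 117 and 1372 genes (low dose, 3.5 h), 901 and 2442 (high dose, 3.5 h), 0 and 5 (low dose, 48 h) and 14 and 57 (high dose, 48 h). The dose differences gave between 0 and 436 at 3.5 h and 0 and 0 at 48 h, the time differences between 0 and 240 (low dose) and 0 and 2 (high dose), and the control channel between 0 and 2649. Without replicate 1 Arg1 reversed to log2 -0.31 at the low dose and 48 h (3.01 without replicate 2), and Tnf to -0.060 at the high dose and 48 h (1.05 without replicate 2). Of 1280 named values with 1 array left out, 922 lost their call, 4 gained one, 352 kept their state and 2 reversed.

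With an estimated correlation 0 of the 83 list calls held. Other settings left the number of calls within 1.5 times, between 81 (files as recorded) and 109 (median centring). With the files as recorded only 33 of the 83 calls were shared, so a like number does not show that the same lists held. Few or no genes passed under that link in most comparisons. The number of list calls with the preset correlation therefore does not tell the recorded from the matched link. Median centring ended 8 list calls and reversed 1, and the matched files under loess ended 5 and reversed 1. Among named genes, no filter ended 137 calls among 473 values, the trended variance 67 among 473, and the strict filter 0 among 376.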

Other observations

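The test of the sample link in this part was chosen after its result was seen, and the list tests were planned. In the control channel several lists differed between 3.5 h and 48 h, with few members past the threshold in each, and time coincided with the slide. Mast cell markers were lower in 2 of 13 genes (2 adjusted over the list alone, median log2 -0.76, adjusted p = 0.00152, and 0.893 with an estimated correlation). Red blood cell markers were lower in 1 of 7 (4 adjusted over the list alone, median log2 -1.09, adjusted p = 0.027, and 0.783 with an estimated correlation), with Hba-a1 at -2.16 ± 0.30. T and NK cell markers had 2 of 21 lower and 1 higher (5 and 1 adjusted over the list alone, median log2 -0.42, adjusted p = 0.0468, and 0.783 with an estimated correlation). Gzma stood at log2 -1.41 ± 0.17 and Cd3d at -1.28 ± 0.18, and the strict filter ended this list's call.

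Mesothelium and fibroblast markers were higher in 1 of 24 genes (2 adjusted over the list alone, median log2 0.67, adjusted p = 0.0165, and 0.783 with an estimated correlation), with Lum at 1.53 ± 0.24. Matrix remodelling had 0 of 26 past the threshold (median log2 0.47, adjusted p = 0.0184, and 0.945 with an estimated correlation). Genes of the unfolded protein response were higher in 2 of 25 (5 adjusted over the list alone, median log2 0.41, adjusted p = 0.0205, and 0.893 with an estimated correlation). Heat shock genes were higher in 2 of 17 (4 higher and 1 lower adjusted over the list alone, median log2 0.42, adjusted p = 0.0247, and 0.893 with an estimated correlation). Cholesterol synthesis was higher in 3 of 25 (4 higher and 2 lower adjusted over the list alone, median log2 0.31, adjusted p = 0.0245, and 0.843 with an estimated correlation). Agilent processed signals ended the calls of matrix remodelling, the unfolded protein response, heat shock and cholesterol synthesis.

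Cytokines in the control channel had 3 of 19 lower (7 adjusted over the list alone, median log2 -0.30, adjusted p = 0.0304, and 0.911 with an estimated correlation). NF-kB targets had 2 of 30 lower and 1 higher (9 and 2 adjusted over the list alone, median log2 -0.47, adjusted p = 0.0339, and 0.946 with an estimated correlation). Simulated data gave 27 false of 185 calls in this comparison, so single genes in it are less certain than elsewhere.

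Several lists were not past the threshold in any comparison with control. At the high dose and 48 h these included lectins, scavenger and phagocytic receptors (4 of 31 higher and 8 lower, median log2 -0.21, adjusted p = 0.379) and alternative activation (2 of 24 higher and 6 lower, median log2 -0.06, adjusted p = 0.528). Large peritoneal macrophages had 3 of 20 higher and 5 lower (median log2 -0.85, adjusted p = 0.0928). Bacterial killing and oxidative burst had 6 of 30 higher and 4 lower (median log2 0.21, adjusted p = 0.495), and the oxidative stress response had 4 of 25 lower (median log2 -0.11, adjusted p = 0.442). Matrix remodelling had 3 of 26 higher and 5 lower, with a median log2 of -0.04, a mean of 0.03 and a test pointing down (adjusted p = 0.788). Neutrophil markers had 3 of 18 higher (median log2 0.09, adjusted p = 0.0862), mast cells 1 of 13 lower (median log2 -0.15, adjusted p = 0.816) and B cells 0 of 17 past the threshold (median log2 -0.46, adjusted p = 0.442). Eosinophil markers had 1 of 9 lower with a median log2 of 0.30, a mean of -0.39 and a test pointing up (adjusted p = 0.917). The unfolded protein response had a median log2 of -0.25 (2 of 25 higher and 1 lower, adjusted p = 0.41), and heat shock -0.03 (1 of 17 lower, adjusted p = 0.887).

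The columns of the value table were set against the scanner files. Controls of the same time and experiment should be alike whatever the dose. Only arrays of the same slide were compared, since under the matched link time coincides with the slide. With files matched to columns by their ratios, the lowest correlation of such control channels exceeded the highest of the other pairs on both slides, by 0.00432 (0.976 against 0.971) and 0.0182 (0.993 against 0.975). With files as recorded the differences were -0.0284 (0.955 against 0.983) and -0.0269 (0.968 against 0.995). This goes with scanner files recorded under the wrong samples, and argues against files recorded rightly with only the columns wrong. Doses exchanged within a pair, or replicate numbers or times exchanged in the column labels, would leave these values unchanged and stay open. No biological explanation was tested, and the poor match of the low dose at 3.5 h, replicate 1, to any file stays open.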
